A study of Rattus norvegicus with 12 samples.

How the data were processed

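RNA from synovial tissue of 12 rats was hybridised to 1-colour (Cy3) arrays, 4 each from normal rats, rats with collagen-induced arthritis and arthritic rats given Bi Zhong Xiao Decoction, per the labels. Groups and replicate numbers were taken from the sample titles. Per the file headers, the authors' scans were quantified with Agilent Feature Extraction 11.0.1.1, which gives a background-subtracted intensity for each spot. The deposited value table holds log2 values of 38620 probes. Set against each array's own log2 intensities, its columns correlated at 0.964 to 0.988 and had the shape of quantile-normalized values with a floor. Their medians were 3.75 on 11 arrays and 2.80 on BZXD replicate 1. On that array 2.80 was also the lowest value, so its median is the floor itself. The centring and the floor's setting are not given in the sources used here.

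The intensities were converted to log2, the spots of one probe were averaged without spots marked as outliers, and each array's 75th percentile over the non-control probes was subtracted. Marked spots made up 0.330% to 3.29% of an array. A probe was kept where it was well above background on at least 4 of the 12 arrays, which left 31288 of 38804 probes, 31247 of them with a value in every group. Of the kept probes, 8566 were not well above background on any BZXD array. On an array, the median SD over the 10 spots of a catalogue probe was 0.124 to 0.216 on the log2 scale. No 2 arrays held the same values: at least 99.9977% of spots differed in every pair. The labels do not say more about the rats than their group and sex, and p-values measure the spread between these samples.

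One limma fit (version 3.58.1, R 4.3.3) over the 12 arrays, with a mean per group and 9 residual degrees of freedom, gave all 3 comparisons. A probe was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Where a probe was well above background on no array of a group, the fold is a lower bound, and where on some arrays, their number is given and the fitted difference rests in part on signals near background, so its size is uncertain. The bound sets the bright group's mean against the mean, over arrays, of the higher of the dim probe's signal and the lowest signal among probes well above background. Figures were drawn with matplotlib. The fit, the groups, the alternatives and the rule for named genes were fixed before the data were examined.

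Of 50 catalogue probes, 48 carry an accession or transcript identifier in the files, and 30 matched the RefSeq table of rat assembly GRCr8, 29 of them with a gene symbol, and the other 38775 probes are unnamed here. No table used here tells messenger from long non-coding probes, so counts are given by the families of probe names only. The rule for named genes took, in each comparison, up to 8 rises and 8 falls among called probes with no overlap between the groups, or the 5 rises and 5 falls with the smallest p where under 5 probes were called. The probes with identifiers printed are among those with the largest rises and falls in the unnamed design probes, without overlap between the groups. The probes named for ultraconserved elements were singled out after seeing the data. Of 34 gene lists with 607 genes fixed beforehand, 3 had any named member on the arrays (Nlrp3, Ldha and Fgf2) and 0 had the 3 needed, so no list was tested.

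The planned normexp correction used the median spot signal and the local background median, with an offset of 50, in place of the mean spot signal, which is not used here. The slide could not be fitted as a block, since each slide holds 1 group. In all, 31 alternatives set beforehand and 12 chosen after seeing the data were run, among them other background corrections, normalizations, filters, thresholds and array sets.

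The fit was tested on simulated data with 29449 probes, drawn independently with each group's own spread. In each comparison 100 probes were changed 2-fold and 100 4-fold. In the data far more probes were called for BZXD, which loosens the adjusted threshold. The shares recovered therefore do not give the power of the BZXD comparisons. For CIA against Control the fit of 12 arrays recovered 35% of changes of 2-fold and 79% of 4-fold, and a fit of 8 arrays 62% and 94%, with 4 and 13 unchanged probes called. For BZXD against CIA the fit of 12 arrays recovered 48% and 80% with 159 unchanged probes called, and a fit of 8 arrays 15% and 54% with 11. In the fit of 12 arrays more unchanged than changed probes were thus called for BZXD. The adjusted threshold therefore did not hold its stated rate of false calls there. The share of false calls among the BZXD calls in the data was not measured. The median SD within a group was 0.177 in Control, 0.201 in CIA and 0.550 in BZXD on the log2 scale, or 0.303 in BZXD without replicate 2. The shared spread is therefore wider than that of Control and CIA and narrower than that of BZXD, in large part through 1 array.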

Results

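Synovial tissue, the membrane that lines the joint, was profiled in rats of 3 groups with 4 arrays each: normal rats (Control), rats with collagen-induced arthritis (CIA), an immunised model of rheumatoid arthritis, and CIA rats given Bi Zhong Xiao Decoction, a herbal preparation (BZXD). Each array measured 38804 probes for messenger and long non-coding RNA in 1 colour. The 75th percentile of probe intensity ran from 54.3 to 69.6 on the Control arrays, from 91.1 to 118 on the CIA arrays and from 24.7 to 32.7 on the BZXD arrays. The share of probes well above background was 73.8% ± 5.98 in Control, 75.8% ± 6.54 in CIA and 49.4% ± 4.10 in BZXD (SD, n = 4 each). No spot was saturated. Each group lay on a slide and in a scan of its own, so slide and group cannot be told apart in any comparison. The precision of every value is limited by the 4 arrays per group.

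Gene names were available here for 29 catalogue probes, of which 17 passed the filter on dim probes. The other 12 named genes stayed below it, among them Nlrp3, the sensor of an inflammasome, Cdh2, a neural and mesenchymal cadherin, and Gdnf, a neurotrophic factor. The remaining design probes carry only identifiers in the sources used here, and are given as counts.

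**Figure D1:**
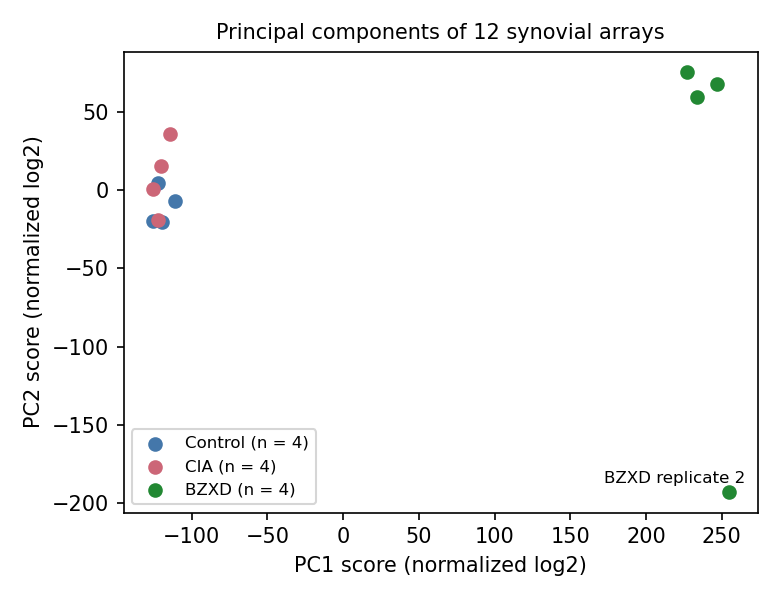
Scores of the 12 arrays on the first 2 principal components of normalized log2 signal, each point 1 array coloured by group. The first component holds 77.3% of the variance and parts BZXD from the other arrays, and the second holds 11.9%, with BZXD replicate 2 at -192.6 and the other BZXD arrays between 59.6 and 75.1.

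The comparison of CIA with Control asks which transcripts differ in the arthritic joint. None of the 17 named genes passed the threshold over all probes, and none passed when adjusted over the named genes alone, whereas in a fit of the 8 Control and CIA arrays 4 passed over all probes and 7 adjusted over the named genes alone. The smallest p on the higher side belonged to Pdk3, a kinase that restrains pyruvate dehydrogenase, at a log2 difference of 0.59 ± 0.18 (SE, n = 4 per group, limma adjusted p = 0.251). Ptk2b, a calcium-responsive tyrosine kinase well above background on 2 of the 4 Control arrays, followed at 0.44 ± 0.25, Cyp2e1, a cytochrome P450, at 0.25 ± 0.16, and Fgf2, a fibroblast growth factor, at 0.16 ± 0.34. On the lower side Map2, a microtubule-associated protein, differed by -0.48 ± 0.16 (adjusted p = 0.288), Eif4b, a translation initiation factor well above background on 3 of the 4 CIA arrays, by -0.54 ± 0.27, the nucleoside transporter Slc28a2 by -0.69 ± 0.35 and the synaptic scaffold Dlg4 by -0.40 ± 0.23. Ldha, the lactate dehydrogenase A subunit, was not well above background on any array of either group. Ndfip1, an adaptor of ubiquitin ligases, stood at 0.17 ± 0.25.

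Over all 31247 tested probes, 4 were called and all 4 were higher in CIA. Among them, ASRN6AP1B100012762V3 differed by 4.06 ± 0.43 on the log2 scale (adjusted p = 0.0277) and was well above background on 2 of the 4 Control arrays, and ASRN6AP1B100035740V3, measured on all 8, by 3.48 ± 0.43 (adjusted p = 0.0368). At an unadjusted p under 0.05 there were 3608 probes, and the 2 groups did not overlap at 20.9% of probes where chance gives 2.86%. With the replicate number as a block in the fit of 12 arrays, 0 probes were called. A fit of the 8 Control and CIA arrays alone called 2933 probes, 717 higher and 2216 lower. With 1 of the 12 arrays left out, the count was 733 without BZXD replicate 2, 8 without CIA replicate 2, 2 without BZXD replicate 4, 1 without CIA replicate 3 and 0 without each of the others. With 1 of the 8 left out it was 66 to 1845, and without Control replicate 4 the split turned to 44 higher and 22 lower. In the fit of 8 arrays, Pdk3 (adjusted p = 0.0363) was higher, and Odf2l (0.0239), Dlg4 (0.0246) and Map2 (0.0427) were lower; Odf2l, a centrosome-related gene, was picked after its value was seen. With 1 of the 8 arrays left out in turn, Pdk3 and Map2 each lost the call in 7 of 8 fits and Dlg4 and Odf2l in 4 of 8, and Map2 also lost it with quantile normalization (0.0625) and the replicate block (0.0520).

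The comparison of BZXD with CIA asks what changed in arthritic rats given the decoction. Of the 17 named genes, 3 rose and 11 fell, and the same numbers passed when adjusted over the named genes alone. With each of the 12 arrays left out in turn, 3 or 4 rose and 9 to 11 fell. Ldha rose at least 36.2-fold: it was well above background on all 4 BZXD arrays and on 0 of the 4 CIA arrays (limma adjusted p = 5.03e-09). Slc28a2 rose by 4.06 ± 0.35 on the log2 scale (SE, n = 4 per group, adjusted p = 7.48e-07), and Eif4b, well above background on 3 of 4 arrays in each group, by 1.33 ± 0.27 (adjusted p = 0.000798). Map2 fell at least 2.63-fold (adjusted p = 3.17e-08) and Cyp2e1 at least 1.94-fold (adjusted p = 4.84e-07), both not well above background on any BZXD array. Fgf2 fell by 1.64 ± 0.34 on the log2 scale (adjusted p = 0.000902), and was well above background on 1 of the 4 BZXD arrays. That array, BZXD replicate 2, was at -2.45, close to the -2.21 to -1.76 of the CIA arrays. The size of the fall thus rests on the BZXD arrays near background.

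**Figure D2:**
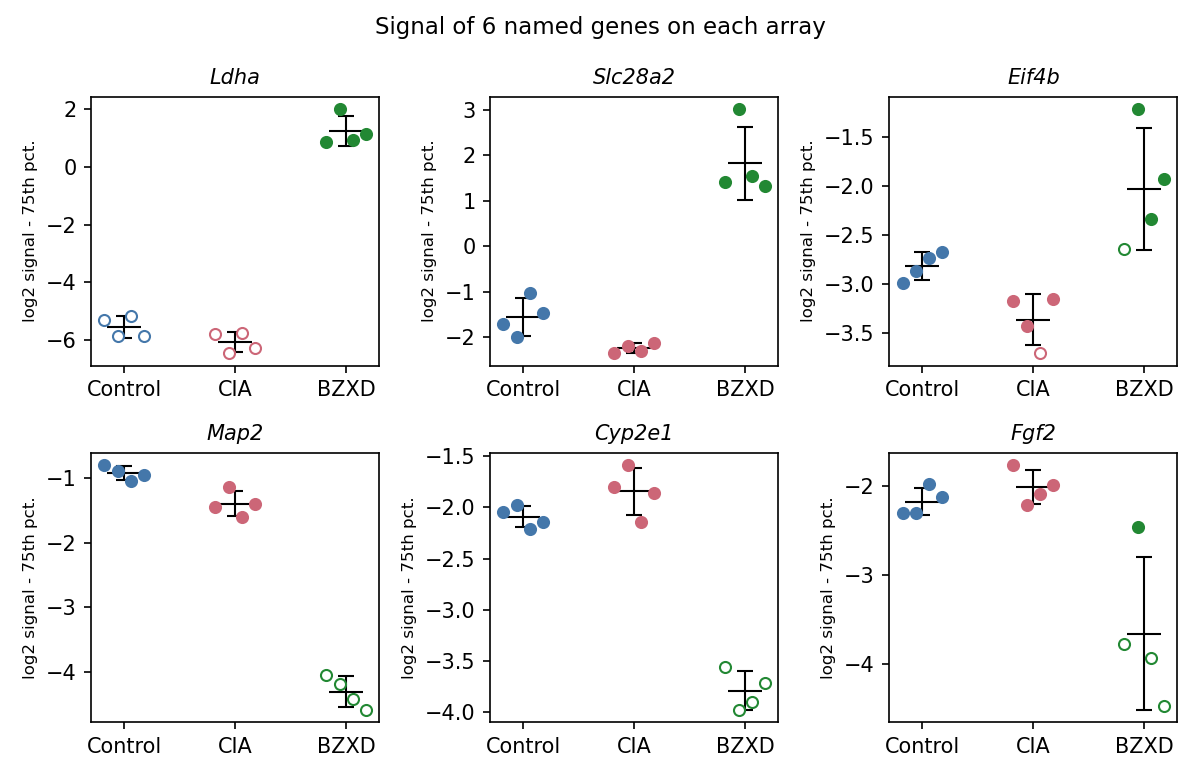
Normalized log2 signal of 6 named genes on each array, relative to that array's 75th percentile, with 1 point per array, filled where the probe was well above background, and bars for the group mean and SD (n = 4). Ldha is open on all Control and CIA arrays and filled on the 4 BZXD arrays, and Map2 is filled on the Control and CIA arrays and open on the BZXD arrays.

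P2rx2, an ATP-gated channel, and Trim2, a ubiquitin ligase, were also lower by the fit but not well above background on any BZXD array, with no fold that can be bounded. Odf2l fell at least 1.1-fold (adjusted p = 0.000921), and Pdk3, well above background on 1 of the 4 BZXD arrays, fell by 0.94 ± 0.18 (adjusted p = 0.000626). The median of all tested probes was itself -0.60. Dlg4, at -0.56 and well above background on 3 of the 4 BZXD arrays, lost the call in 11 of the 12 fits with an array left out, and stood at -0.82 without BZXD replicate 2, the fit in which it was called. Ptk2b, not well above background on any BZXD array, lost it in 5 of the 12, without CIA replicate 1, 2 or 4 or BZXD replicate 3 or 4. Pdcd10, Pop7 and Ppp2r2b did not pass, at 0.60 ± 0.29, 0.56 ± 0.36 and -0.07 ± 0.42, and Pdcd10 and Ppp2r2b were well above background on 3 of the 4 BZXD arrays. Without BZXD replicate 2, Pop7 stood at 0.10 ± 0.11 and Ppp2r2b passed at 0.48 ± 0.11 (adjusted p = 0.00254), and without BZXD replicate 1 Pdcd10 passed at 0.88 ± 0.24 (adjusted p = 0.00626). Under a background correction with an added offset, the falls of Map2, Cyp2e1, Fgf2, P2rx2, Odf2l, Trim2 and Pdk3 turned into rises, whereas the rises of Ldha, Slc28a2 and Eif4b kept their direction in all settings run. The sizes depended on the setting: under that correction Ldha, Slc28a2 and Eif4b rose by 2.10, 1.99 and 0.85 on the log2 scale, Ldha then below the bound given for it. In fits added after seeing the data, normexp followed by quantile normalization gave 1.84, 1.92 and 0.30 for these rises and -0.39 for Map2, and the fall of Odf2l was not past the threshold there (adjusted p = 0.0638), nor that of Pdk3 there (0.0771) or in the fit of 8 arrays with quantile normalization (0.0895).

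In simulated data the fit of 12 arrays called more unchanged than changed probes for BZXD against CIA, so its adjusted p-values may be too small. A fit of the 8 BZXD and CIA arrays alone called 21843 probes. In the fit of 12 arrays, 23355 of 31247 probes were called, 8539 higher and 14816 lower in BZXD. Among them, ASRN6AP1B100061498V3 rose by 9.52 ± 0.56 on the log2 scale (adjusted p = 5.01e-08), and ASRN6AP1B100001925V3 fell by 7.39 ± 0.78 (adjusted p = 4.14e-06) and was well above background on 1 of the 4 BZXD arrays. Higher calls made up 36.6% of these, and 76.2% under the offset correction. Of 541 tested probes whose names follow the numbering of ultraconserved elements, 82 were higher and 315 lower in BZXD, so that 20.7% of the calls were higher. This share was 20.2% in the probes with ASRNV in their names (602 higher, 2376 lower), 26.1% in those with ASRN6LNC (575 higher, 1624 lower) and 41.0% in those with ASRN6AP (7247 higher, 10413 lower). Across all 959 probes named for ultraconserved elements the share well above background was 50.8% ± 6.81 in Control, 55.3% ± 7.83 in CIA and 26.5% ± 3.65 in BZXD (SD, n = 4 each). Over all probes on the array it was 73.8%, 75.8% and 49.4%, so the lower share in BZXD is not particular to this family.

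**Figure D3:**
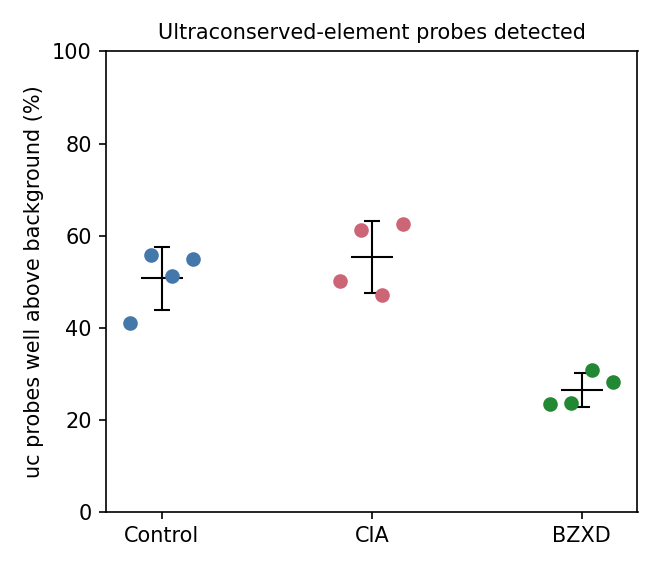
Percent of the 959 probes named for ultraconserved elements that were well above background on each array, with 1 point per array and bars for the group mean and SD (n = 4). The means are 50.8% in Control, 55.3% in CIA and 26.5% in BZXD, against 73.8%, 75.8% and 49.4% over all probes.

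The comparison of BZXD with Control asks how far decoction-treated rats lay from normal rats. Among the named genes 3 rose and 9 fell, with the same numbers when adjusted over the named genes alone, and 3 or 4 rose and 8 to 11 fell with each array left out in turn. Ldha rose at least 28.5-fold (limma adjusted p = 6.70e-09), Slc28a2 by 3.37 ± 0.35 on the log2 scale (SE, n = 4 per group, adjusted p = 3.28e-06) and Eif4b, well above background on 3 of the 4 BZXD arrays, by 0.79 ± 0.27 (adjusted p = 0.0194). Map2 fell at least 3.66-fold (adjusted p = 1.24e-08), Cyp2e1 at least 1.63-fold (adjusted p = 1.40e-06), Odf2l at least 1.60-fold (adjusted p = 8.29e-05) and P2rx2 at least 1.11-fold (adjusted p = 2.10e-06). Fgf2 fell by 1.48 ± 0.34 on the log2 scale and Med16, a subunit of the Mediator complex, by 1.08 ± 0.26, each well above background on 1 of the 4 BZXD arrays. On that array, BZXD replicate 2, Fgf2 was at -2.45 against -2.30 to -1.98 in Control, and Med16 at -2.06 against -1.98 to -1.87. Both sizes thus rest on the BZXD arrays near background. Dlg4, well above background on 3 of the 4 BZXD arrays, fell by 0.96 ± 0.23. Trim2 was also lower by the fit but not well above background on any BZXD array. The fall of Med16 was not past the threshold with quantile normalization (adjusted p = 0.0758) or median scaling (adjusted p = 0.0596), and that of Dlg4 was not with median scaling (adjusted p = 0.0869). In fits of 8 arrays added after seeing the data, Eif4b was not past it with the replicate block (0.0541), nor Fgf2 (0.0933), Trim2 (0.0858) and Med16 (0.146) with quantile normalization. With normexp and quantile normalization, also added, Fgf2 (0.0927) and Med16 (0.0833) were not past it. The offset correction turned the falls of Odf2l, Cyp2e1, P2rx2, Fgf2, Trim2 and Med16 into rises, and left Map2 lower, at -0.14. It put Dlg4 at 0.044, not past the threshold (limma adjusted p = 0.348). Under it Ldha, Slc28a2 and Eif4b rose by 1.72, 1.63 and 0.50, and Eif4b rose by 1.35 with quantile normalization and 0.51 without BZXD replicate 2. Without that array Ppp2r2b (0.50), Pdk3 (-0.43) and Ptk2b (-0.47) also passed, against a median of -0.66 over all probes in that fit. Pdk3 and Ptk2b were then not well above background on any BZXD array left, so the sizes of their falls are not measured. Pdcd10 (0.65) passed without BZXD replicate 1. Ndfip1 lost the call in 5 of the 12 fits, without Control replicate 1 or 2 or BZXD replicate 1, 3 or 4.

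A fit of the 8 BZXD and Control arrays alone called 22716 probes. In the fit of 12 arrays, 23929 of all tested probes were called, 8440 higher and 15489 lower, against a median of -0.69. Higher calls were 35.3% of these, 45.6% with median scaling and 74.2% under the offset correction. Among the probes named for ultraconserved elements 88 were higher and 315 lower. Correlations over the 12220 probes well above background on all 12 arrays ran from 0.687 to 0.766 between Control and BZXD arrays, from 0.658 to 0.771 between CIA and BZXD arrays, and from 0.952 to 0.991 between Control and CIA arrays.

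Whether the decoction opposed the changes of CIA was asked by counting probes called in both comparisons with opposite signs. Of the 4 probes higher in CIA, 2 were lower in BZXD than in CIA and 1 was higher still, where independent lists give 1.90 and 1.09. No named gene was among them. Both comparisons use the CIA arrays. Across probes, which are not independent replicates, the log2 differences of the 2 comparisons had a Pearson correlation of -0.18 where shared arrays alone gave -0.50 in 100 simulations. The simulated arrays had no group difference, and the large differences of BZXD shrink a correlation, so these 2 values cannot be set against each other. Their covariance was -0.18 against a simulated -0.09. The simulated spread was the shared one, wider than that of CIA, so -0.09 overstates what the shared arrays give. With the CIA arrays split 2 against 2, the correlation lay between -0.17 and -0.04 over the 6 assignments. With the 8 arrays of each comparison fitted alone the count was 908, with 1121 probes going the same way. Of these 908, 362 rose in CIA and fell in BZXD and 546 fell and rose, where independent lists give 318 and 565. Without BZXD replicate 2 the count was 369, with 269 the same way, and the 2 opposed parts were 144 and 225 where independent lists give 127 and 149.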

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

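All tests of explanations in this part were chosen after the result was seen. Of 66 groups of 4 values examined, 6 held an array far from its group by Dixon's ratio, and chance gives about 1 in 20 groups. Control replicate 3 had Pop7, a subunit of ribonuclease P, at -0.87 against -0.72 to -0.69 on the other Control arrays (ratio 0.839), and Trim2 at -3.16 against -3.39 to -3.36 (ratio 0.831).

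BZXD replicate 2 accounts for the other 4. Its second principal component was -192.6 against 59.6 to 75.1 (ratio 0.942), Pop7 was 1.19 against -0.68 to -0.61 (0.964), Slc28a2 3.02 against 1.32 to 1.53 (0.876), and Ppp2r2b, a phosphatase subunit, -3.94 against -1.81 to -1.63 (0.923). Admixture of Control or CIA RNA stays open. Its median correlation with those 8 arrays was 0.658, below the 0.727 or more of the other BZXD arrays. With the other BZXD arrays it was also low, 0.880 against 0.974 or more, so a low correlation cannot decide. Single genes went both ways. Med16 was at -2.06, within the CIA range of -2.11 to -1.87 and above the -3.47 to -3.17 of the other BZXD arrays. Map2 was at -4.19, within the -4.59 to -4.04 of the other BZXD arrays. Uneven hybridisation stays open: its spot SD of 0.175 lay within the 0.152 to 0.216 of the other BZXD arrays, but 3.29% of its spots were marked as outliers, against 0.823% to 2.02%. A difference of the animal or its dissection was not tested.

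The BZXD arrays stood apart from all others, with 23355 probes called against CIA. Of 35 splits of the 8 arrays 1 reached that count, the fewest possible, and the highest other called 232. A split that mixes the groups puts their gap into the spread within its parts, so it calls few probes whatever the gap's source. The splits therefore show only that the calls follow group and slide. Against Control 23929 were called, again in 1 of 35 splits, with 0 in the highest other. Dimness alone is argued against by bright probes, over which the highest correlation of a BZXD array with a Control or CIA array was 0.771, below the lowest between BZXD arrays, 0.839. The 10 adenovirus E1A control probes, which have no rat target, differed by a median of -1.31 between BZXD and CIA, but at mean intensities of at most 263 they may be unspiked and take up rat RNA. An effect of the decoction and one of the slide cannot be told apart, as 0 slides hold BZXD and another group.

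CIA and Control differed at 4 probes in the fit of 12 arrays. Of the 35 splits 1 reached this count and the highest other gave 2. In the fit of 8 arrays 1 of 35 reached 2933, with 1 in the highest other. A share of 1 in 35 is the lowest that these splits can give. For the 4 calls, set against 2, chance is therefore not excluded. The 2933 calls follow the division into groups, which is also the division into slides. The splits take no account of the replicate number, with which as a block the 4 calls became 0, and 8 of the 12 fits with an array left out also gave 0. For the 2 opposed probes chance cannot be excluded, since 2 of 35 splits gave as many and the highest other also gave 2. Of the E1A control probes 40% passed an unadjusted p of 0.05 in either fit, against 11.6% of all kept probes in the fit of 12 arrays and 30.3% in the fit of 8, gaps that a slide difference could give. With 10 probes and each slide holding 1 group, arthritis and slide cannot be told apart.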

How the results depend on the processing

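The 12 settings that combine the fit of 8 arrays or normexp with a second choice, or leave out arrays from the fit of 8, were chosen after seeing the data. The slide as a block and the list tests were not run. For CIA against Control, 4 probes were called, and also 4 with the intensity trend or a fold of 2 added. The count was 14700 with normexp, 15 with quantile normalization, 18 with median scaling, 500 with the deposited value table, 31 with no filter, 0 with probes well above background on all 12 arrays (fewer probes tested), 2933 with the 8 arrays compared, 6469 with array weights, 869 at an unadjusted p with a fold of 2, and 0 against a fold of 1.5. The added settings gave 154 with normexp and quantile normalization, and for the 8 arrays 3354 with the trend, 2831 with quantile normalization and 1809 with the replicate block. Leaving out 1 array gave 0 to 733, the highest without BZXD replicate 2, and in the fit of 8 arrays 66 without Control replicate 4 to 1845 without CIA replicate 4. Except where a smaller set of probes or arrays is named, the cause was not tested.

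With an array left out, BZXD against CIA gave 22110 to 25327 calls and BZXD against Control 22817 to 26028. Only the filter on all 12 arrays moved them over 1.5 times, to 9091 and 9135, with 12220 probes tested in place of 31247. Of these calls 53.4% and 53.1% were higher, with a median of 0.13 and 0.14 over the probes tested. A probe that falls to background on BZXD cannot pass that filter, so it takes out falls. Normexp left the counts within 1.5 times but turned the share of higher calls from 36.6% to 76.2% and from 35.3% to 74.2%.

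The 2 opposed probes became 13498 with normexp, 9 with quantile normalization, 12 with median scaling, 227 with the value table, 25 with no filter, 0 with the filter on all 12 arrays, 908 with the 8 arrays, 2496 with array weights, 460 at an unadjusted p and 0 against a fold of 1.5. Added settings gave 65 with normexp and quantile normalization, and for the 8 arrays 1062 with the trend, 960 with quantile normalization and 661 with the replicate block. Leaving out an array gave 0 to 369, and the 6 splits of the CIA arrays gave 0, 7, 9, 0, 0 and 0.

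With the replicate number as a block, CIA against Control gave 0 calls, BZXD against CIA 23409, BZXD against Control 24002 and the opposed count 0. Same-numbered arrays deviated together at 0.077 to 0.573 between Control and CIA, -0.128 to 0.132 between Control and BZXD and -0.079 to 0.297 between CIA and BZXD, so not every pair was over 0.1, and Control replicate 4 went best with CIA replicate 2 (0.431). The samples share only a number, which is also the position on the slide.

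For the genes taken by the rule, direction turned under normexp alone. For CIA against Control the log2 difference became -0.065 for Pdk3, -0.21 for Ptk2b, -0.12 for Cyp2e1 and -0.16 for Fgf2. For BZXD against CIA it became 0.16 for Map2, 0.33 for Cyp2e1, 0.42 for Fgf2, 0.57 for P2rx2, 0.55 for Odf2l, 0.65 for Trim2 and 0.44 for Pdk3. For BZXD against Control it became 0.21 for Odf2l, 0.21 for Cyp2e1, 0.29 for P2rx2, 0.26 for Fgf2, 0.36 for Trim2, 0.23 for Med16 and 0.044 for Dlg4. The median of all probes moved from -0.60 to 0.49 and from -0.69 to 0.27. The offset of 50 exceeds the 75th percentile of every BZXD array, and with quantile normalization after normexp none of these genes turned. On the BZXD arrays 49.4% of probes were well above background, which limits the folds of the others to bounds.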

Other observations

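The opposite-strand test below was set out before its result was seen. Several named genes did not follow what their general use in cells would lead one to look for. Ldha, an enzyme of glycolysis in most tissues, was not well above background on any of the 8 Control and CIA arrays, while Map2 and Dlg4, best known from neurons, were well above it on all 8. Each gene is read here by only 1 named probe, so a weak probe cannot be told from a low transcript. Magoh, a core part of the exon junction complex, and Cse1l, a nuclear export factor, were each above background on 1 of the 12 arrays. For both it was BZXD replicate 2, the array flagged above as far from its group. Enpp1 and Ndfip2 were likewise above background on that array alone.

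One hypothesis was that the BZXD arrays carried label of the opposite strand, which would exchange the signal of probes on the 2 strands of an element. Over 141 ultraconserved elements with at least 1 strand well above background in each group, the plus minus strand difference in BZXD correlated with that in Control at 0.853 (Spearman 0.855), across elements, which are not independent replicates. The same strand was the brighter in 87.2% of elements, and in 96.5% between CIA and Control. The result goes against an exchange of strands.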
